A study of Homo sapiens with 12 samples.

How the data were processed

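The data are 2 tables of raw counts per gene deposited by the authors, 1 for each experiment, with 6 libraries each. Per the labels' protocols, total RNA of RT4 cells was made into libraries with a strand-marking kit. Per the file headers, the authors counted read pairs of the overexpression libraries over exons with featureCounts 2.0.1 against the Ensembl release 107 annotation of GRCh38, from alignments whose names hold the word hisat, with no strand option, so reads of a gene and of an overlapping or antisense gene cannot be told apart. The aligner's version, and the aligner, counter, annotation and strand setting of the resistance table, are not given in the sources used here, and the genome build is hg38 per the submitters' processing notes. All 37 mitochondrial genes are listed at 0 in the overexpression table, while they hold 1.81% of the counts of the resistance table, so no mitochondrial transcript was compared there.

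Groups were taken from the sample titles, except for the parental columns, which are headed NC with a number. No title of a parental sample holds that name. They were taken as parental because they share a table with the resistant columns, while the vector controls have columns in the other table. This assignment is an inference. No label ties their numbers to a sample, so they are called parental libraries a, b and c. They are not the vector libraries: over 8188 well-expressed genes, log2 CPM correlated at 0.819 to 0.823 between parental and vector libraries and at 0.998 among the parental libraries. No pair of replicates agreed within sampling noise, since the chi-square per degree of freedom over genes was 1.54 to 12.2. Nothing says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

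Symbols came from a table of gene names, which held 61757 of 61860 identifiers of the overexpression table and 62700 of 62700 of the resistance table. The 103 others took 0.143% of the counts. Positions are those of GENCODE 29, on the same assembly, counted from 1.

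Genes passing edgeR's filterByExpr were tested per experiment with TMM factors and the quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested. Genes with an adjusted p under 0.05 are called changed. Adjusted p-values of genes come from this test, and those of lists from camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists, unless an estimated correlation is named. The difference between the experiments was tested in 1 fit of all 12 libraries with 4 group means, over genes in both tables. Changes over 1.5-fold were tested with glmTreat. Intervals of ratios resting on few counts are exact binomial at 95% and cover counting error only.

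The 33 gene lists, with 721 genes that all matched a symbol, and the rule for named genes were fixed before the data were examined. The rule takes ITGB4, STAT3, CDKN1A, MDM2 and ITGA6, then the 6 largest increases and the 6 largest decreases among called genes with a mean of at least 1 CPM and no overlap between the groups' libraries, leaving out pseudogenes, antisense and unnamed loci, then up to 3 called members of each list with the smallest p, or 2 abundant members of a list with none. Between the experiments it takes, for each pair of signs alike or opposite, the 5 genes called in both with the largest smaller change. Some genes that the rule takes, and 1 of the lists, are not reported here.

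The procedure was tested on simulated data with the real means, dispersions and library sizes and 200 changed genes outside the lists, in 5 simulations. For the overexpression comparison, over 16624 genes, it recovered 58.5% of 1.25-fold, 67.9% of 1.5-fold, 86.1% of 2-fold and 99.6% of 4-fold changes, and 7.99% of its calls were unchanged genes. For the resistance comparison, over 16465 genes, the shares were 39.3%, 63.0%, 78.3% and 96.2%, with 9.34% of calls unchanged. For the difference between experiments, over 15652 genes, 82.6% of differences of at least 2-fold were recovered. False calls were thus somewhat above the nominal 5% with 200 changed genes. The real comparisons called 72.2% of genes for overexpression and 54.5% for resistance, so these shares do not carry over to them. No unchanged list was called in 160 and 165 list tests, and a list of changed genes was called in 5 of 5 simulations of each. The simulated genes were drawn independently of each other, while estimated correlations within the real lists reached 0.76. These list tests thus cannot show how often lists of genes that vary together are falsely called.

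The alternatives were other scalings, DESeq2 1.42.0, limma-voom, other low-count filters, a fold threshold, a fit of all libraries, a replicate block, other list tests and leaving out each library.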

Results

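RNA was sequenced from RT4 cells, an established human bladder cancer line, in 2 experiments of 6 libraries each. The first experiment compared 3 libraries of cells given an empty vector with 3 libraries of cells given a plasmid for Flag-tagged ITGB4, the beta 4 integrin subunit that pairs with ITGA6 in hemidesmosomes. The second compared 3 libraries of parental cells with 3 libraries of a cisplatin-resistant line. Its labels also give the parental libraries a treatment with PBS and the resistant ones a treatment with cisplatin, a platinum drug that crosslinks DNA, with no dose or time. Total counts lay between 22701466 and 33352045 per library in the first experiment and between 31824582 and 38199946 in the second. The series title names ITGB4, STAT3 and cisplatin among others, so the transcripts of ITGB4 and STAT3 and the known targets of STAT3 were followed in both comparisons. Values are TMM-normalised CPM, counts scaled to library size, as mean ± SD with n = 3 per group. After a log2 fold change from 3 against 3 libraries, ± gives its size divided by the square root of the test's F statistic. This approximates a standard error for modest changes only. For large changes resting on few counts it can be much smaller than the counting error, as for PRKAR2B below.

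The overexpression experiment asks which transcripts change when ITGB4 is raised. ITGB4 itself was 1.64-fold higher in the cells given its plasmid, at 1427 ± 53.6 CPM against 869 ± 10.97 CPM (SD, n = 3), a log2 fold change of 0.71 ± 0.026 (adjusted p = 2.22e-13). Interferon-stimulated genes rose with it: 28 of 31 tested members were higher and 1 was lower, with a median 2.63-fold increase. Genes of hypoxia and glycolysis rose as well, 18 of 19 being higher. NRF2 and glutathione genes went the other way, with 22 of 26 lower, though the call of that list was lost with an estimated correlation (adjusted p = 0.11). Among all 16950 genes tested, 6185 were higher and 6049 lower, and 3818 passed a test for a change over 1.5-fold, 1880 of them higher and 1938 lower. Of the called genes, 2746 changed over 2-fold, more than ITGB4 itself. The rise of ITGB4 thus does not by itself show that it drove the other changes.

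ITGB4 (ENSG00000132470) lies on chromosome 17 from 75721328 to 75757818 on the plus strand of GRCh38, as a protein-coding gene in GENCODE 29. All 3 plasmid libraries, at 1485, 1379 and 1416 CPM, lay above the 3 vector libraries, at 858, 879 and 871 CPM. On the same assembly, ITGA6 (ENSG00000091409) lies on chromosome 2 from 172427354 to 172506282, STAT3 (ENSG00000168610) on chromosome 17 from 42313324 to 42388568, CDKN1A (ENSG00000124762) on chromosome 6 from 36676460 to 36687339, and MDM2 (ENSG00000135679) on chromosome 12 from 68808176 to 68850686. A count of exon reads cannot separate plasmid from endogenous ITGB4 transcripts. ITGA6, its partner, was 1.20-fold higher (log2 0.27 ± 0.026, adjusted p = 7.18e-08). The transcript of STAT3, a transcription factor downstream of cytokine receptors, had a log2 fold change of -0.04 ± 0.023 (adjusted p = 0.141). It was called lower with library sizes alone, at -0.08 (adjusted p = 0.00501). MDM2, which encodes a ubiquitin ligase, was 1.80-fold higher at 585 ± 34.4 against 325 ± 9.20 CPM (adjusted p = 1.34e-12). CDKN1A, which encodes the cell cycle inhibitor p21, was lower by a factor of 1.20 at 303 ± 3.65 against 363 ± 3.71 CPM (adjusted p = 4.76e-08).

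**Figure D1:**
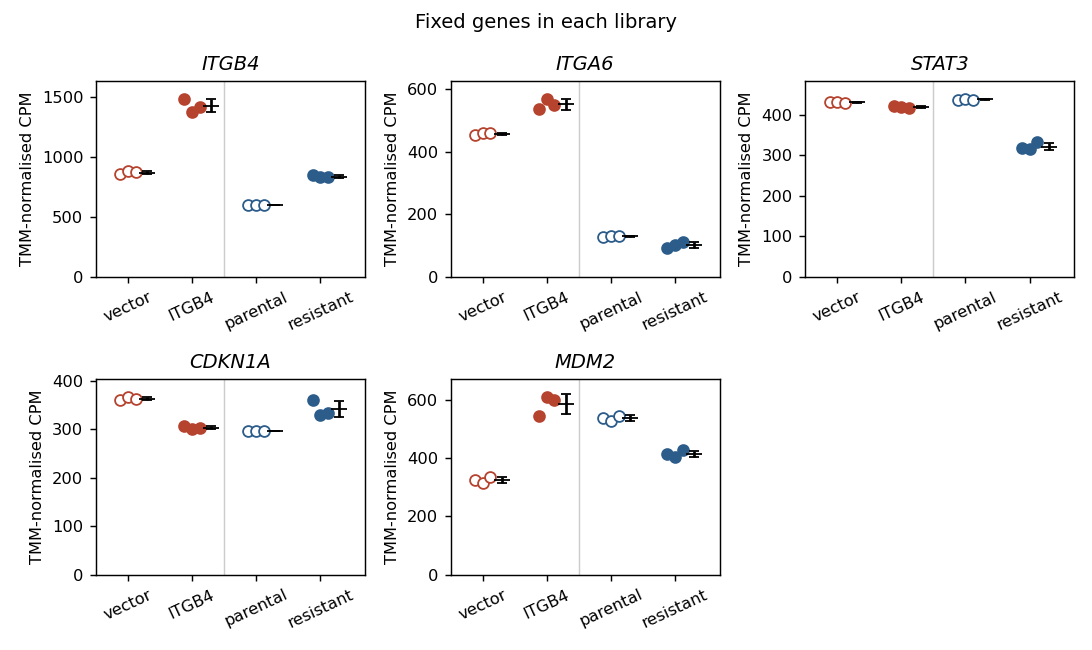
TMM-normalised CPM (linear vertical axes from 0) of ITGB4, ITGA6, STAT3, CDKN1A and MDM2 in each library, with open circles for vector and parental libraries, filled circles for plasmid and resistant libraries, and the mean ± SD (n = 3) beside each group. ITGB4 lay at 1379 to 1485 CPM in the 3 plasmid libraries, above all 3 vector libraries, and averaged 837 CPM in resistant against 600 CPM in parental cells.

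The largest increases by the fixed rule were those of FCGR3B, PLA2G4D, CEACAM5, CEACAM6, SCN3A and CXCL11. PLA2G4D, a cytosolic phospholipase A2, went from 0.370 ± 0.024 to 61.0 ± 2.08 CPM (log2 7.34 ± 0.089). CXCL11, an interferon-induced chemokine, went from 11.96 ± 1.04 to 1012 ± 22.5 CPM (log2 6.41 ± 0.043). CEACAM5, a carcinoembryonic antigen on the cell surface, rose by 7.28 ± 0.14 on the log2 scale. FCGR3B rested on 2 counts in all vector libraries together against 363, a ratio of 206 with an exact 95% counting interval of 56.5 to 1700, and SCN3A on 3 against 290, a ratio of 109 (37.1 to 534). CEACAM6 had 4 counts against 579, a ratio of 164 (63.7 to 604). Reads of FCGR3B, CEACAM5 and CEACAM6 can be shared with close paralogs, so these values are uncertain.

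The largest decreases were those of C2CD4A, NEUROD4, RNF150, FOSB, PRKAR2B and C11orf96. C2CD4A fell from 65.8 ± 0.428 to 0.554 ± 0.184 CPM (log2 -6.89 ± 0.088). FOSB, an immediate-early AP-1 subunit, fell from 86.3 ± 1.55 to 1.33 ± 0.036 CPM (log2 -6.01 ± 0.064). RNF150 had a log2 fold change of -6.10 ± 0.21 and PRKAR2B, a regulatory subunit of protein kinase A, one of -5.50 ± 0.30. PRKAR2B rested on 325 counts against 6, a ratio of 47.8 with a counting interval of 21.7 to 131. NEUROD4 had 826 counts in the vector libraries and 7 in the plasmid libraries, and C11orf96 had 181 and 4. Without plasmid replicate 2 the log2 fold change of NEUROD4 was -7.26, and without vector replicate 3 that of SCN3A was 7.33 against 6.59 in all libraries.

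Among the interferon-stimulated genes, the antiviral effectors OASL, IFIT2 and RSAD2 rose 20.6-fold to 1988 ± 65.4 CPM, 15.3-fold to 1402 ± 4.77 CPM and 13.4-fold to 2167 ± 26.9 CPM. The list differed from all other genes by camera (adjusted p = 3.18e-101), and did so with an estimated correlation (adjusted p = 0.00058). Antigen presentation genes rose in 9 of 10, including NLRC5, an activator of class I genes, and B2M (camera adjusted p = 0.00452, and adjusted p = 0.113 with an estimated correlation). NF-kB targets and cytokines moved apart. CXCL10, also induced by interferon, rose by 4.94 ± 0.028 on the log2 scale, while the chemokines CCL20 and CXCL3 were among 13 of 18 lower members (camera adjusted p = 0.000563, and adjusted p = 0.11 with an estimated correlation).

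Hypoxia and glycolysis genes rose, with the glycolytic enzymes HK2 (log2 1.74 ± 0.026) and LDHA (1.44 ± 0.023) and the mitophagy receptor BNIP3 (2.09 ± 0.033) among them. The list had camera adjusted p = 2.85e-22 and adjusted p = 0.0494 with an estimated correlation. Nuclear genes of oxidative phosphorylation were lower in 29 of 32 and higher in 2, with a median log2 fold change of -0.31 (adjusted p = 0.000563, and adjusted p = 0.323 with an estimated correlation). Of the NRF2 and glutathione genes GCLC, which encodes the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, fell from 1873 ± 16.5 to 538 ± 2.66 CPM, while AKR1B10 rose by 1.45 ± 0.030 on the log2 scale (list adjusted p = 1.87e-08, and adjusted p = 0.11 with an estimated correlation). All 5 tested members of the metallothionein and zinc list rose, with MT2A, a metal-binding protein, 9.55-fold higher (adjusted p = 1.45e-05, and adjusted p = 0.091 with an estimated correlation). Reads of metallothioneins and aldo-keto reductases can be split among close relatives. The amino acid response genes PSAT1, SLC7A5 and MTHFD2 were among 12 of 19 lower members (adjusted p = 3.01e-08, and adjusted p = 0.111 with an estimated correlation). HSPA5, the chaperone BiP, DNAJB9 and HERPUD1 were among 12 of 16 lower ER chaperone genes (adjusted p = 1.31e-05, and adjusted p = 0.091 with an estimated correlation).

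Basal and squamous genes rose in 16 of 19, with the keratin KRT6A, whose reads can be shared with KRT6B and KRT6C, going from 1.27 ± 0.202 to 99.9 ± 5.41 CPM. The cornified envelope genes SPRR1A and IVL rose by 3.34 ± 0.093 and 2.57 ± 0.077 on the log2 scale (list adjusted p = 1.03e-07, and adjusted p = 0.11 with an estimated correlation). DNA replication genes rose in 28 of 31, among them RRM2, a subunit of ribonucleotide reductase, UHRF1 and FEN1, with a median 1.65-fold change (adjusted p = 1.25e-09, and adjusted p = 0.091 with an estimated correlation). Crosslink and excision repair genes rose in 30 of 39, among them BRIP1, FANCI and BRCA2 (adjusted p = 0.000626, and adjusted p = 0.136 with an estimated correlation). Mitotic genes were lower in 15 and higher in 9 of 29, with KIF20A, a kinesin of cell division, at -1.47 ± 0.039 (adjusted p = 0.0287, and adjusted p = 0.136 with an estimated correlation). ERK output genes were lower in 11 of 16, among them the MAP kinase phosphatases DUSP5 and DUSP4, and higher in 3, among them EMP1 (adjusted p = 0.000363, and adjusted p = 0.111 with an estimated correlation). Cholesterol and fatty acid genes were lower in 21 of 30, with SCD, a fatty acid desaturase, at -1.39 ± 0.021 (adjusted p = 0.00102, and adjusted p = 0.091 with an estimated correlation). Ribosome biogenesis genes were higher in 12 of 19 (adjusted p = 0.023, and adjusted p = 0.4 with an estimated correlation).

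Of single genes taken by the rule, the pro-apoptotic gene PMAIP1 was higher (log2 1.16 ± 0.031), and BTG2 (-1.52 ± 0.026) and PLK2 (-1.63 ± 0.029) were lower. The STAT3 targets had 10 higher and 10 lower of 24, the lower ones including FOS (-3.25 ± 0.040), PIM1 (-1.46 ± 0.025) and MYC (-1.34 ± 0.027). Their camera adjusted p was 0.0408, and adjusted p = 0.136 with an estimated correlation. The call was also lost without plasmid replicate 1, 2 or 3 (adjusted p = 0.0501, 0.0624 and 0.0576) and with the filter at 1 CPM (adjusted p = 0.0526). Integrin, hemidesmosome and laminin genes other than ITGB4 had 9 higher, among them COL17A1 and LAMA3, and 9 lower, among them DST (adjusted p = 0.946), with a median of -0.04, a mean of 0.03 and an upward test. Platinum and copper transport genes had 11 lower, among them ABCC4, ABCC5 and the copper importer SLC31A1, and 4 higher of 18 (adjusted p = 0.0512). Adjusted over the list alone, each of these lists gave the counts above, except 16 lower mitotic genes and 4 higher and 22 lower cholesterol genes.

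The replicates of this experiment differed little, with a common biological coefficient of variation of 2.65%, and nothing in the labels says that they came from separate cultures. In both groups a label of the second library names ITGB5 and one of the third names ITGB6 in place of ITGB4, while all titles name ITGB4. In plasmid libraries 1, 2 and 3, ITGB5 lay at 58.6, 51.7 and 55.4 CPM, below all vector libraries and lowest in the library whose label names it. ITGB6 lay there at 87.4, 96.3 and 96.9 CPM, above the vector libraries at 76.6, 79.2 and 76.7 CPM (log2 0.27 ± 0.038, adjusted p = 6.42e-06). It was highest in the library whose label names it, close to the second. So neither library stood apart by a rise of the gene its label names. ITGB4 lay at 1485, 1379 and 1416 CPM in plasmid libraries 1, 2 and 3. ITGB5 and ITGB6 were chosen after their values were seen.

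The resistance experiment asks how cisplatin-resistant RT4 cells differ from parental ones, with cisplatin on one side and PBS on the other. Mitotic genes were lower in all 28 tested members, with a median log2 fold change of -1.55: AURKA, a spindle kinase, fell from 145 ± 2.85 to 32.5 ± 0.949 CPM and CDC20, an activator of the anaphase-promoting complex, from 127 ± 2.36 to 27.5 ± 0.563 CPM (SD, n = 3). NF-kB targets and cytokines were lower in 15 of 17 and higher in 0. ITGB4 was 1.40-fold higher at 837 ± 9.37 against 600 ± 2.09 CPM (log2 0.48 ± 0.033, adjusted p = 1.45e-09). Of 16875 genes tested, 4520 were higher and 4679 lower, and 2107 passed the test for a change over 1.5-fold, 1042 higher and 1065 lower.

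CDKN1A was 1.15-fold higher in resistant cells at 341 ± 16.7 against 296 ± 0.591 CPM (adjusted p = 0.000458), and MDM2 was lower at 414 ± 11.6 against 537 ± 9.28 CPM (adjusted p = 1.44e-07). STAT3 was lower at 322 ± 9.24 against 438 ± 1.29 CPM (adjusted p = 1.74e-08). ITGA6 was lower at 102 ± 9.34 against 130 ± 1.60 CPM (adjusted p = 4.19e-05).

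The largest increases were those of LAMA1, ASPA, SULT2A1, PRODH, APLP1 and PGF. SULT2A1, a hydroxysteroid sulfotransferase, went from 0.135 ± 0.040 to 7.59 ± 0.414 CPM (log2 5.79 ± 0.25), and PGF, placental growth factor, from 1.23 ± 0.107 to 25.7 ± 5.00 CPM. LAMA1, a laminin chain, rested on 4 counts in the parental libraries against 294, a ratio of 69.9 with a counting interval of 27.0 to 258. All 4 lay in parental library b. Without it the parental count was 0 and the fitted log2 fold change, which then hangs on the prior count, was 9.60 against 5.99. ASPA, aspartoacylase, had 4 counts against 284, a ratio of 67.5 (26.1 to 250). PRODH, proline dehydrogenase, stood at 4.57, 1.08 and 0.440 CPM in the resistant libraries, and its log2 fold change of 5.05 ± 0.89 was 3.66 without resistant replicate 1 and 6.80 without parental library a. APLP1 had a log2 fold change of 4.63 ± 0.35, and 5.41 without parental library a.

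The largest decreases were those of BCL2A1, SERPINB7, A2ML1, CSF3, PI3 and TNFAIP6. BCL2A1, an anti-apoptotic BCL2 relative, fell from 10.8 ± 0.505 to 0.230 ± 0.061 CPM (log2 -5.55 ± 0.20). PI3, the elastase inhibitor elafin, fell from 391 ± 2.10 to 14.8 ± 0.507 CPM. CSF3, a granulocyte growth factor, fell from 25.4 ± 1.81 to 0.822 ± 0.534 CPM, with a log2 fold change of -4.94 that was -5.61 without resistant replicate 2. SERPINB7 changed by -5.43 ± 0.23, A2ML1 by -4.97 ± 0.27 and TNFAIP6 by -4.57 ± 0.12 on the log2 scale.

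PLK1, another mitotic kinase, was 4.18-fold lower among the mitotic genes, which differed from all other genes by camera (adjusted p = 3.73e-73, and adjusted p = 0.00229 with an estimated correlation). DNA replication genes did not follow them: 17 were higher and 6 lower of 31, with the helicase subunits MCM5 and MCM6 2.37-fold and 2.44-fold higher and PCNA, the sliding clamp, 1.66-fold higher (adjusted p = 0.00452, and adjusted p = 0.173 with an estimated correlation). RPS27L rose by 1.49 ± 0.056, DDB2, a damage sensor of excision repair, by 1.70 ± 0.071 and CYFIP2 by 1.85 ± 0.084 on the log2 scale. Crosslink and excision repair genes had 11 higher and 16 lower of 39, with BRIP1, BARD1 and FANCI lower (adjusted p = 0.78).

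**Figure D2:**
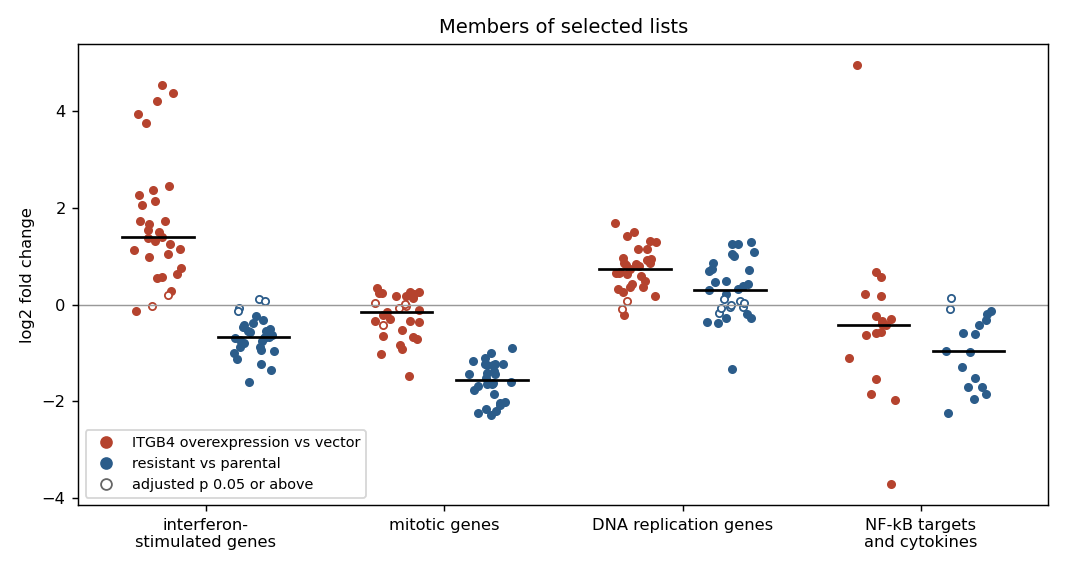
Log2 fold changes (vertical axis) of the tested members of 4 gene lists, in red for ITGB4 overexpression against vector and in blue for resistant against parental cells, with bars at the medians and open circles where the adjusted p was 0.05 or above. Interferon-stimulated genes had medians of 1.40 and -0.66, and mitotic genes of -0.15 and -1.55.

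CXCL8, a neutrophil chemokine, fell from 1311 ± 14.3 to 341 ± 12.3 CPM, among NF-kB targets. TNFAIP3, an inhibitor of NF-kB, and BIRC3 were 3.24-fold and 3.25-fold lower (list adjusted p = 1.36e-20, and adjusted p = 0.0262 with an estimated correlation). Interferon-stimulated genes were lower in 27 and higher in 0 of 31, with OAS1 at 1702 ± 51.5 against 3399 ± 16.9 CPM and SAMD9 and RSAD2 at log2 -1.23 ± 0.044 and -0.96 ± 0.036 (adjusted p = 1.35e-18, and adjusted p = 0.111 with an estimated correlation). Antigen presentation genes were lower in 7 of 9, with B2M and CIITA among them (adjusted p = 0.0141, and adjusted p = 0.355 with an estimated correlation). The STAT3 targets were lower in 17 and higher in 3 of 23, with the adhesion molecule ICAM1 at 1.62 ± 0.126 against 12.5 ± 0.368 CPM and OSMR and BIRC5 lower (adjusted p = 4.55e-05, and adjusted p = 0.111 with an estimated correlation). BIRC5 is also a mitotic gene. Apoptosis regulators were lower in 14 of 23, with CFLAR, an inhibitor of caspase-8, at -1.20 ± 0.042 (adjusted p = 5.89e-05, and adjusted p = 0.0631 with an estimated correlation). Basal and squamous genes were lower in 14 of 21, with S100A8 at 10.2 ± 0.927 against 123 ± 1.80 CPM and S100A9 and SPRR1A lower (adjusted p = 7.19e-07, and adjusted p = 0.111 with an estimated correlation).

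NRF2 and glutathione genes were lower in 19 of 26, with AKR1B10, AKR1C1 and PGD at log2 -2.19 ± 0.048, -1.63 ± 0.038 and -1.43 ± 0.037 (adjusted p = 2.21e-10, and adjusted p = 0.111 with an estimated correlation). Integrin, hemidesmosome and laminin genes other than ITGB4 were lower in 14 of 22, among them ITGB8 and LAMB3 (adjusted p = 0.0029, and adjusted p = 0.212 with an estimated correlation). Cholesterol and fatty acid genes were lower in 18 of 30 (adjusted p = 0.000979, and adjusted p = 0.149 with an estimated correlation). Cytosolic ribosomal protein genes were higher in 42 of 46, by a median of 1.27-fold (adjusted p = 2.38e-10, and adjusted p = 0.458 with an estimated correlation). Ribosome biogenesis genes were higher in 17 of 19 (adjusted p = 1.62e-06, and adjusted p = 0.0631 with an estimated correlation). Amino acid response genes were higher in 13 of 19, among them TRIB3 and SESN2 (adjusted p = 6.91e-05, and adjusted p = 0.212 with an estimated correlation). Nuclear oxidative phosphorylation genes were higher in 21 of 32 (adjusted p = 0.00616, and adjusted p = 0.683 with an estimated correlation), as were 8 of 13 mitochondrially encoded mRNAs (adjusted p = 0.00847, and adjusted p = 0.271 with an estimated correlation). Epithelial junction genes were lower in 11 of 20 (adjusted p = 0.0383, and adjusted p = 0.18 with an estimated correlation), a call lost with library sizes alone (adjusted p = 0.0938). Of 16 drug transport genes 4 were higher, among them the efflux pumps ABCC3 and ABCG2, and 6 lower, among them ABCC1 (list adjusted p = 0.727).

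Adjusted over the list alone, the counts in the resistance experiment stayed as given, except for 13 higher crosslink repair genes, 5 higher and 8 lower drug transport genes, 7 lower DNA replication genes, 8 lower antigen presentation genes, 1 higher NF-kB target, 18 higher ribosome biogenesis genes and 9 higher mitochondrially encoded mRNAs. With library sizes alone in place of TMM factors the median of all genes moved from 0.02 to 0.18 on the log2 scale and the split of calls to 6548 higher and 3111 lower, so the directions above are relative to the bulk of genes.

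The last comparison set the changes of both experiments side by side, to see whether raised ITGB4 and cisplatin resistance move the same transcripts. Genes called in both mostly changed in opposite directions. Of these 7018 genes, 4697 (66.9%) had opposite signs, and of 592 that changed over 2-fold in both, 489 (82.6%) did. The 2 control groups also differed from each other, so this does not show that raised ITGB4 and resistance act in opposite ways. ITGB4 was higher in both, by 0.70 and 0.49 on the log2 scale in the fit of all 12 libraries, a difference of 0.21 ± 0.041 (adjusted p = 0.00017). MDM2 moved up in one and down in the other (difference 1.20 ± 0.054, adjusted p = 7.21e-14), and so did CDKN1A in the reverse order (-0.49 ± 0.048, adjusted p = 1.86e-08). The 2 log2 fold changes of STAT3 differed by 0.39 ± 0.040 (adjusted p = 5.46e-08) and those of ITGA6 by 0.60 ± 0.063 (adjusted p = 5.79e-08).

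CSF3 rose with ITGB4 overexpression from 3 counts in all vector libraries to 236, a ratio of 89.1 with a counting interval of 30.1 to 435, and changed by -4.94 ± 0.22 on the log2 scale in resistant cells. Its fitted rise of 6.29 was 7.03 without vector replicate 3, and its fall -5.61 without resistant replicate 2. NOS2, the inducible nitric oxide synthase, went by 3.42 ± 0.04 and -3.82 ± 0.05, SERPINB7 by 3.13 ± 0.20 and -5.43 ± 0.23, and PGLYRP3, a peptidoglycan recognition protein, by 3.43 ± 0.29 and -3.43 ± 0.26. Without vector replicate 3 the rise of PGLYRP3 was 4.18. DHRS2 went the other way, by -3.33 ± 0.09 and 3.57 ± 0.11. KRT75, a keratin, rose in both, by 2.71 ± 0.11 and 3.69 ± 0.14, as did OTOF, by 3.86 ± 0.19 and 1.70 ± 0.08. PGLYRP2, DOCK4 and FBLN5 were lower in both, PGLYRP2 by -3.12 ± 0.22 and -3.59 ± 0.16.

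**Figure D3:**
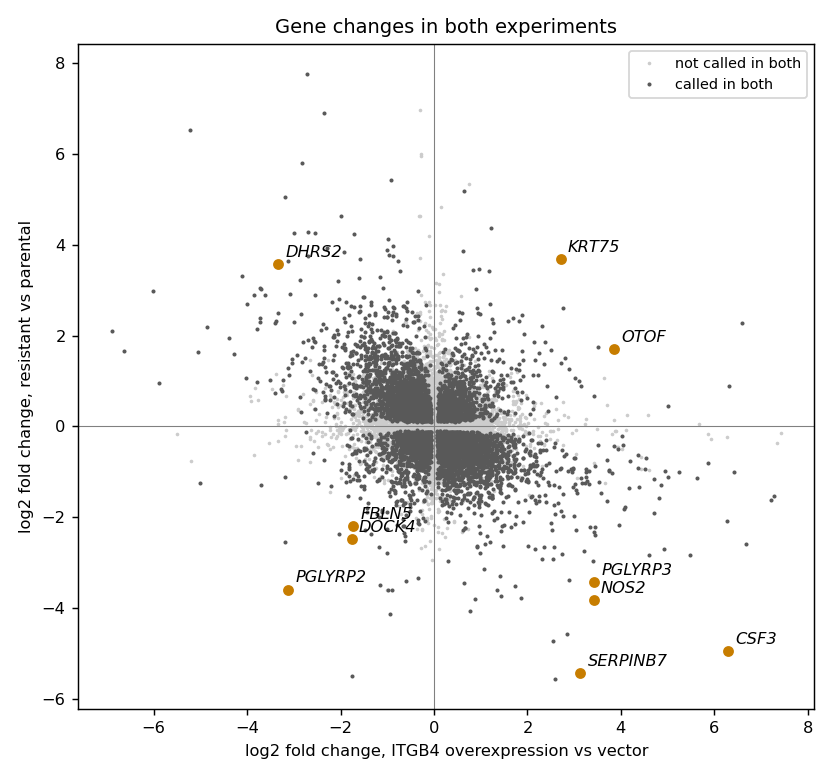
Log2 fold change of each of 15655 genes tested in both experiments, with ITGB4 overexpression on the horizontal and resistance on the vertical axis, dark points for genes called in both and orange points for the 10 named genes. More of the called genes lie in the upper left and lower right quadrants, 2104 and 2593, than in the upper right and lower left, 1113 and 1208.

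Independent lists would have shared 1737 genes higher with ITGB4 overexpression and lower in resistance, where 2593 were found, and 1528 the other way round, where 2104 were found. They would have shared 1623 genes higher in both, where 1113 were found, and 1635 lower in both, where 1208 were found. Fisher's exact test across genes, two-sided, gave p = 1.83e-207, 8.61e-101, 5.48e-82 and 1e-56, as a description, since genes are not independent replicates. Pearson's r of the log2 fold changes across genes was -0.31 and Spearman's rho -0.28, and Pearson's r was -0.13 with DESeq2 fold changes. In a fit of all 12 libraries the change differed between the experiments for 11442 of 18516 genes. Per the labels the experiments used different media, and they were counted and deposited in separate tables, so these differences also hold whatever set the experiments apart.

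**Figure D4:**
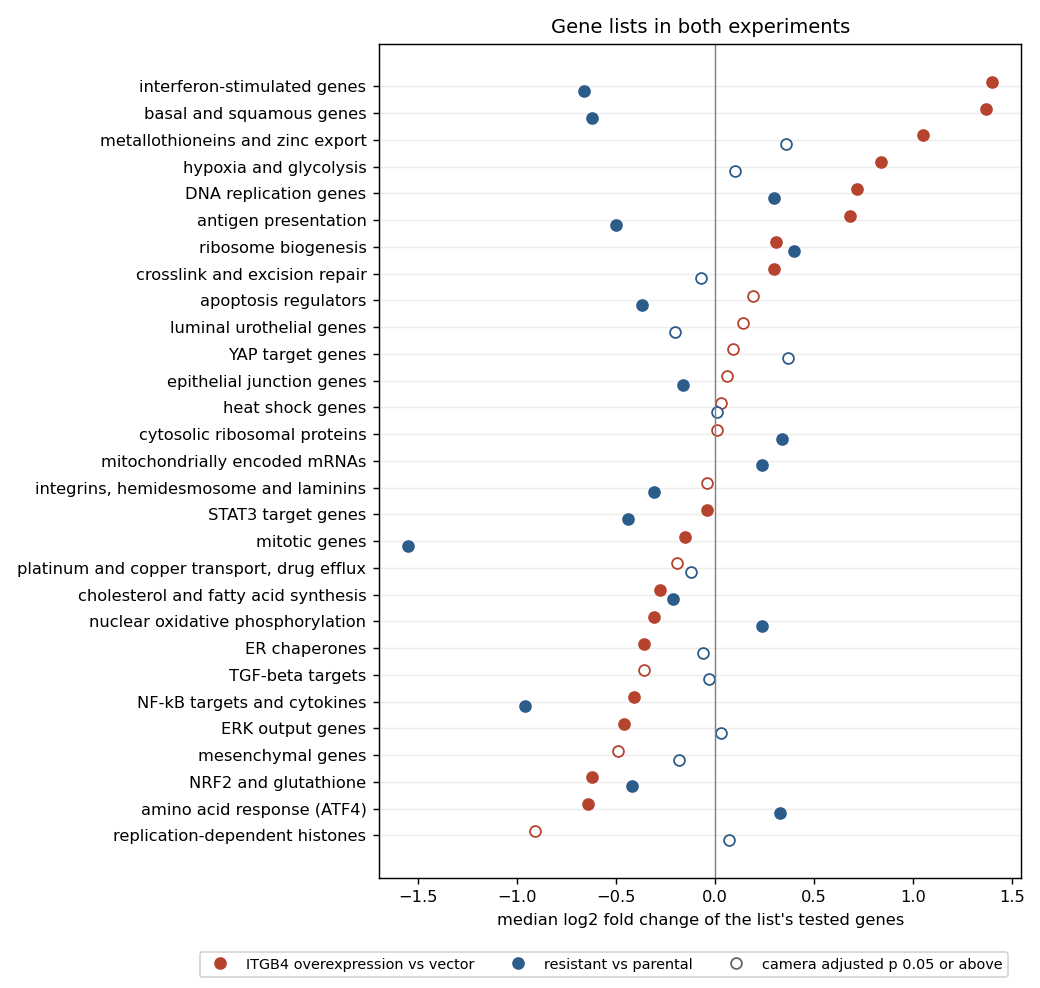
Median log2 fold change (horizontal axis) of the tested genes of each list reported here with at least 5 tested genes in the resistance experiment, in red for ITGB4 overexpression and in blue for resistance, with filled circles where the camera adjusted p was under 0.05. Interferon-stimulated, basal and squamous, and antigen presentation genes lay to the right in red and to the left in blue.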

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

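The removal of GC trends was chosen after the data were seen, with its bounds set before its values, and tests of leukocyte markers and of fewer cycling cells, and the splits within each experiment, were chosen only after the result was seen. The 10 results below were picked out because the difference between the changes in both experiments was itself past the threshold while the changes had opposite signs, though the experiments are not the same treatment. Groups of 3 libraries were not searched for outlying samples.

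The median over genes of the difference in log2 fold change, overexpression minus resistance, was 2.99 for basal and squamous genes, 2.02 for interferon-stimulated genes, 1.15 for antigen presentation genes, -0.83 for amino acid response genes and -0.60 for nuclear oxidative phosphorylation genes. With an estimated correlation the adjusted p of these differences was 0.0202, 0.000531, 0.104, 0.0396 and 0.356. The single genes were CSF3 (11.21, resting on 3 counts in the vector libraries), SERPINB7 (8.54), NOS2 (7.22), PGLYRP3 (6.85) and DHRS2 (-6.93).

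The rise of interferon-stimulated genes with ITGB4 overexpression was weighed first. With each library's trend on GC content removed, their median log2 fold change was 1.40, as before, which argues against that trend. Leukocyte markers summed to 14.8 ± 0.948 CPM in the plasmid and 22.5 ± 0.688 CPM in the vector libraries, a ratio of 0.66, nearly all of it ITGAM (14.0 CPM in the plasmid and 21.9 CPM in the vector libraries), while the pan-leukocyte gene PTPRC had at most 2 counts in any of the 6 libraries, which argues against leukocytes. The vector libraries control for plasmid delivery as such. A response to raised ITGB4 and a difference between the groups in the amount of plasmid taken up or in culture state stay open, since the groups do not separate them. A high level was also seen without the plasmid. RSAD2 lay at 2952 to 2973 CPM in the parental libraries of the other experiment, and at 2136 to 2185 CPM in the plasmid libraries. ITGB4 was at 598 to 602 CPM in those parental libraries, below the vector libraries. The experiments differ in media and counting, so levels were not tested between them.

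The fall of mitotic genes in resistant cells was weighed next. With GC trends removed their median was -1.48. Of 10000 random lists matched on length, GC content and expression, 0 had a median as low, the lowest being -0.43, so gene length, GC or expression class does not account for it. Fewer cycling cells alone would lower DNA replication genes as well. Their median was 0.30, and its 95% bootstrap interval over genes, -0.01 to 0.49, reached just below 0 but lay above that of the mitotic genes, -1.73 to -1.31, which argues against fewer cycling cells as the sole cause. Fewer cycling cells together with another change in replication genes, a block between replication and mitosis, and exposure to cisplatin itself, which the labels give only to the resistant libraries, may be candidates and were not tested.

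The opposite changes in both experiments were weighed last. Pearson's r across genes was -0.32 with GC trends removed, which argues against GC trends. It was -0.32 over the 15041 genes outside the fixed lists, so it was not confined to the listed genes. Over the 8893 genes with at least 10 CPM in both it was -0.32 too. The experiments share no libraries, so independent noise of low genes would weaken r rather than make it negative. That last test thus could not decide. A culture state that differs in opposite directions in the 2 experiments may be a candidate, and neither it nor a biological link was tested. The 2 control groups also differed from each other. Log2 CPM correlated at 0.819 to 0.823 between parental and vector libraries. Within the experiments it correlated at 0.903 to 0.907 between vector and plasmid and at 0.931 to 0.942 between parental and resistant libraries. MDM2 averaged 537 CPM in parental libraries, nearer the plasmid (585 CPM) than the vector libraries (325 CPM). CDKN1A did likewise, at 296 CPM against 303 and 363 CPM. ITGB4 and ITGA6, at 600 and 130 CPM in parental libraries, lay below both groups. STAT3, at 438 CPM, lay nearer the vector (431 CPM) than the plasmid libraries (420 CPM). What these unlike baselines add to the opposite signs was not tested.

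Regrouping the 6 libraries of an experiment gives 10 splits, too few for a share under 0.05. The real split called 12234 genes for ITGB4 overexpression and 9199 for resistance, and the highest of the others called 0 in each. For gene lists the real splits called 17 and 18, and the highest others 14 and 10. Every other split called at least 8 lists, though it called 0 genes. The number of lists called thus sets the real grouping apart far less than the number of genes does. For the 7018 genes called in both experiments, the highest other of 100 combined splits gave 0, which follows from the 0 genes above and decides nothing further. For the difference between experiments, 1 of 100 drawn splits, the real one, reached 11442 genes. The highest other, 9634, was the real grouping with 1 experiment's labels turned over, and the next was 4836. Without the turned-over grouping the median of the others was 0. Other splits mix treated with control libraries, which widens the spread within groups and lowers the calls, so this count decides little further.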

How the results depend on the processing

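The removal of GC trends was chosen after seeing the data, and the other alternatives before. Against a change of over 1.5-fold (glmTreat) 3818 genes were called for ITGB4 overexpression and 2107 for resistance, by construction a stricter test. With an estimated correlation, camera called 2 lists (interferon-stimulated, and hypoxia and glycolysis) instead of 17 for overexpression. For resistance it called 3 (mitotic and NF-kB among them) instead of 18. The test fry, which does not compare a list with other genes, called 28 for overexpression and also more than 18 for resistance. Fry gave hypoxia and glycolysis in resistance the opposite direction (adjusted p = 0.011), and the cause was not tested. Library sizes alone turned the log2 fold change of HSP90AA1 in resistance to 0.006. That scaling moves all genes of a library alike, and the median of all genes went from 0.02 to 0.18. 
STAT3 after ITGB4 overexpression, not called, was called with library sizes alone (-0.08), the stricter filter (-0.06) and GC trends removed (-0.08). The drug transport list after overexpression was called, besides fry, with 6 of the alternatives (adjusted p = 0.0099 to 0.0485), apoptosis regulators after overexpression with no low-count filter (adjusted p = 0.0259), and YAP targets in resistance with 4 (adjusted p = 0.0373 to 0.0494). VWF lost its call with DESeq2 (adjusted p = 0.0735).

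Leaving out each library kept the number of genes called at 11696 to 12389 for overexpression and 8331 to 9024 for resistance. With the replicate number as a block in the overexpression experiment 12070 genes were called, and the numbers did not pair the libraries (correlations of same-numbered deviations -0.02, -0.02 and -0.01). No paired analysis was possible because the parental columns carry no replicate number tied to a sample, so the block was not run for resistance, the difference or the overlap. With DESeq2 in both, 6038 genes were called in both, 68.5% with opposite signs, while r over all its genes was -0.13.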

Other observations

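The lists below were not called by camera, with adjusted p = 0.0994 for YAP targets in resistance as the lowest. After ITGB4 overexpression, mesenchymal genes had 3 higher, among them FN1, and 6 lower, among them SNAI2 at -2.38 ± 0.037 on the log2 scale, of 10 tested. Luminal urothelial genes had 11 higher and 8 lower: UPK1B rose by 1.42 ± 0.031 and FGFR3, a receptor tyrosine kinase, changed by -1.02 ± 0.030, and in resistant cells these changed by -1.29 ± 0.061 and 1.29 ± 0.046, where 7 luminal genes were higher and 12 lower. In resistance 3 mesenchymal genes were higher and 3 lower. YAP targets had 6 higher and 5 lower after overexpression and 7 higher and 4 lower in resistance, with FJX1 at -2.61 ± 0.034 and 1.74 ± 0.069. TGF-beta targets had 3 higher and 6 lower, and 4 higher and 3 lower, with TGFBI at 3.16 ± 0.15 in resistance. Apoptosis regulators had 13 higher and 6 lower after overexpression, with BCL2 at -2.01 ± 0.053, and epithelial junction genes 9 higher and 6 lower.

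Heat shock genes had 3 higher and 3 lower after overexpression and 4 higher and 3 lower in resistance. Replication-dependent histones had 1 higher and 7 lower of 11, and 2 higher and 2 lower of 13. Cytosolic ribosomal protein genes had 11 higher and 16 lower of 46 after overexpression. In resistance ERK output genes had 6 higher and 6 lower, hypoxia and glycolysis genes 6 higher and 7 lower, ER chaperones 5 higher and 8 lower, and metallothionein and zinc genes 1 higher and 2 lower, with MT2A at -0.93 ± 0.060. Of 3 tested fibroblast markers 2 were higher and 1 lower in each experiment. The leukocyte marker ITGAM was lower in both, and of 3 endothelial markers 1 was higher and 1 lower after overexpression and 1 higher in resistance. Adjusted over the list alone, the counts were the same except 7 higher YAP targets and 15 lower ribosomal protein genes after overexpression, and 8 higher luminal genes, 7 higher ERK output genes and 4 lower TGF-beta targets in resistance. Median, mean and test differed in sign after overexpression for YAP targets (0.09, 0.13, down), heat shock genes (0.03, -0.03, down), ribosomal proteins (0.01, -0.03, down) and fibroblast markers (0.77, 0.08, down). In resistance they differed for metallothioneins (0.36, 0.07, down), mesenchymal genes (-0.18, -0.02, up), TGF-beta targets (-0.03, 0.32, down), histones (0.07, -0.10, up), endothelial markers (-0.09, 0.83, up) and drug transport genes (-0.12, 0.00, up). Within groups, deviations correlated with GC content at 0.61 and -0.59 in plasmid replicates 1 and 2 and at 0.55 in resistant replicate 1.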
